A study of Mus musculus with 6 samples.

How the data were processed

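RNA abundance was measured by sequencing of total RNA in 6 samples of mouse male germline stem cells. Per the labels' protocols, the cells had been grown on DR4 feeder fibroblasts, ribosomal RNA was depleted, and strand-specific libraries were sequenced on an Illumina NextSeq500. The labels name 2 populations, CDH1+/THY1+ and CDH1-/THY1+, with 3 samples each, which carry the culture names RP7, RP5 and WT1 in both populations.

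Per the submitters' processing notes, the tools were Trimmomatic 0.32, TopHat2 2.1.1, featureCounts with Subread 1.5.0-p3, and DESeq2 1.12.3 in R 3.3.1, on mouse build GRCm38.p4. The annotation release, the counting settings and the model formula were not given in the sources used here, so it is not known whether the authors' test treated the culture as a block, or whether the counting used strand. Reads of near-identical family members and of overlapping or antisense genes could have been split or assigned in ways that cannot be checked from the values.

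The data analysed here were 1 table of the authors' own comparison with 22432 rows, 1 per Ensembl gene. The authors' mean normalised count of each gene is a signal that is never negative: read counts divided by a size factor per library and averaged over all 6 libraries. The fold change and its standard error were deposited on the log2 scale, the Wald statistic was deposited as a score, and the table holds a deposited p-value and an adjusted p-value per gene. The statistic equalled the fold change divided by its standard error to within 2e-07. Standard errors did not exceed 0.640 even for genes with a mean count near 1. This is a sign that the deposited fold changes had been shrunken towards 0. They therefore understate changes of genes with few reads, and may do so for abundant genes with standard errors near that limit. The columns hold only the comparison and no value per library. No SD per group, no fit of a model to the reads and no leaving out of a library was run. The number of libraries that show the direction of a change is likewise unknown.

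The direction, CDH1+/THY1+ over CDH1-/THY1+, was taken from the name of the table. Cdh1, the gene of the sorted surface protein, was not analysed here, so the direction has no check in the values, and every "higher" and "lower" in the text rests on that name.

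Gene symbols, positions, exon lengths and GC content came from GENCODE release M21, which has the coordinates of GRCm38, matched on the Ensembl identifier without its version. A symbol was found for 22317 rows and not for 115. Genes with an adjusted p-value under 0.05 in the authors' deposited table were called higher or lower. The adjusted p-value was empty in 3221 rows. Of these, 3119 had a p-value and a mean count of at most 2.51, the remaining 102 had no p-value.

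An adjusted p-value by the Benjamini-Hochberg method equals the p-value times the number of tests divided by the rank, so the number of tests was recovered as the whole number that makes every rank whole. It was 19743, against 19211 rows with an adjusted p-value. The difference of 532 tested genes was not analysed here. The ranks also gave the number of genes called among all tests, 6970. A read in 1 library adds a fixed amount to a mean count, so the differences between the 1734 mean counts under 1.6 were searched for the amounts of 6 libraries. With the 6 amounts found, 100% of those rows were whole reads, to within 2e-07. The amounts gave size factors from 0.913 to 1.08, a ratio of 1.18 between the highest and the lowest. For 6347 of the 6350 rows with a mean count under 8 a single set of whole reads per library matched the mean count to within 3e-09. These reads were used only to compare unnamed libraries for genes with few reads. The libraries carry no names, and none was assigned to a population or a culture. The total count per sample is therefore unknown. The mean normalised counts of the rows sum to 16900379, as a mean over all 6 libraries, and the median gene had a mean count of 97.5.

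Before the data were examined, 29 gene lists were fixed: cell type markers, germ cell stages, pluripotency, signalling, adhesion, cell state, metabolism and RNA quality. The lists hold older and current symbols of some genes, so a listed symbol without a row can be a second name. Each list was tested against all other genes with a p-value by limma's cameraPR (limma 3.58.1, R 4.3.3) on the deposited Wald statistic, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. A correlation cannot be estimated without values per library, so a preset correlation of 0.05 was run in its place. Beside the test stand the number of members called over all genes, the number called when the adjustment ran over the list alone, and the percentile of the list's median among 10000 random lists matched on mean count in 25 bins. For genes with a mean count of at least 50 the standard error was ranked among the 200 genes of nearest mean count. A list's median rank was compared with random lists, for which 0.0002 is the smallest p-value the 10000 draws can give. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

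The rule for the genes named was also fixed before the data were examined. It took Cdh1, Thy1, Hprt and Xist, the 10 highest and 10 lowest fold changes among called genes with a mean count of at least 100 and a symbol other than a predicted gene's, and up to 4 members of each list with the smallest adjusted p-values. Some genes chosen by this rule are not reported here. Fits to raw counts and the leaving out of single cultures had been planned only for the case that the table held counts per sample, and were not run. The alternatives run were other thresholds, other adjustments, minimum mean counts and fold changes, lists with members left out, other list statistics, and, added after the data were seen, the removal of a trend with exon length and GC content, of genes with large standard errors, and of the lowest fold changes.

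The steps were tested on simulated data. The standard errors of the 22330 genes with a p-value were kept, 200 genes were given known log2 changes of 0.5, 1 or 2, and the others none. The calls recovered 16.4%, 46.3% and 66.7% of the changes of these sizes, and 0.023% of the unchanged genes were called. With so few changed genes the adjustment is stricter than in the real comparison, so these shares do not give its sensitivity. With 12 of the called genes removed from the simulated table, the search returned 22330 tests and 12 absent genes. The list test called 5 of 5 simulated lists that had been shifted by 1 on the log2 scale and 0 of 45 unchanged lists. The simulated genes were drawn independently, so this does not show how often the test calls unchanged lists of correlated genes. Of 200 simulated rows of whole reads, 199 were recovered exactly.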

Results

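Total RNA was sequenced from 6 samples of cultured male mouse germline stem cells, the self-renewing cells that maintain sperm production and can be propagated on fibroblast feeders. The cells had been sorted by 2 surface proteins: CDH1, the cell adhesion molecule E-cadherin, and THY1, a glycoprotein used to enrich germline stem cells. There were 3 CDH1+/THY1+ and 3 CDH1-/THY1+ samples, at passage 6 to 8. Each population came from cultures named RP7, RP5 and WT1, labelled with ages of 8 weeks, 19 days and 5 weeks. RP7 and RP5 carried the strain label OCT4/GFP and Dox-OCT4, and WT1 the label C57BL/6. The values were those of the authors' deposited table, in which 11173 of 22432 genes had a mean normalised count of at least 100. Size factors of the 6 libraries, worked out from the spacing of the low mean counts in the authors' deposited table, ranged from 0.913 to 1.08. Depth per sample and spread within each population are unknown, and the standard errors given are those of the authors' test. A value after a gene name, written with ±, is its log2 fold change, CDH1+/THY1+ over CDH1-/THY1+, with that standard error.

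The comparison asked how RNA levels differ between THY1+ germline stem cells with and without surface CDH1. CDH1+/THY1+ cells had lower levels of germ cell genes, among them the piRNA pathway genes Tdrd1 and Mov10l1, the spermatogonial factors Zbtb16 and Dmrt1, and the meiotic genes Mei1 and Sycp3. They had higher levels of the pluripotency-associated genes Sox2, Tbx3 and Zfp42, of fibroblast marker genes such as Fn1 and Cald1, of glycolytic enzymes such as Ldha and Pfkl, and of cell cycle genes such as Rrm2 and Cdk1. The pluripotency and glycolysis lists lost their call under an alternative that kept the germ cell identity call. Without genes of large standard errors for their mean count, cameraPR no longer called the naive pluripotency list (adjusted p = 0.729) or the glycolysis list (0.0773). That alternative kept 4 of 12 and 10 of 18 members of these lists, against 28 of 34 for germ cell identity, so it was not an equal test. Of 19211 genes of the authors' deposited table with an adjusted p-value, 6438 (33.5%) were called at an adjusted p under 0.05 by DESeq2. In CDH1+/THY1+ cells 3292 were higher and 3146 lower. Of these, 1435 were higher and 1256 lower by at least 2-fold. The median log2 fold change of all genes was 0.01. The rows ended at a log2 fold change of 2.14 (4.41-fold) on the higher side and reached -2.94 (7.68-fold lower) on the other. The adjusted p-values came from 19743 tests, and the 532 tested genes not analysed here all had an adjusted p under 0.05. The counts of higher and lower genes therefore cover the rows analysed and not the whole comparison. The same holds for the counts, medians and tests of the gene lists. A Benjamini-Yekutieli adjustment over all genes with a p-value left 1666 higher and 1967 lower genes, and an adjusted p under 0.01 left 2107 and 2313. The former ran over 22330 genes and not over the authors' 19743 tests, so calls lost under it reflect the changed set of genes as well.

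**Figure D1:**
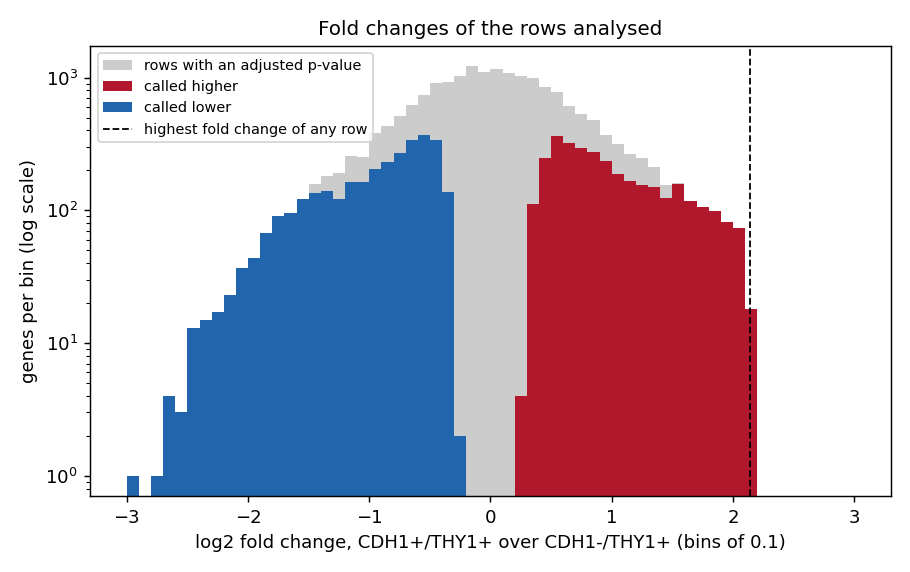
Number of genes per 0.1 of log2 fold change, CDH1+/THY1+ over CDH1-/THY1+, on a log axis, for the rows of the authors' deposited table with an adjusted p-value (grey), called higher (red) and called lower (blue). The higher side ends at 2.14 (dashed line), and the lower side reaches -2.94.

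Among called genes with a mean count of at least 100, the 10 highest fold changes lay close together, just under that end of the table. They are the highest of the rows analysed, and called genes not analysed here may lie above them. In the authors' deposited table Rdm1, a gene of the RAD52 motif family (chromosome 11, 101627195 to 101636100 in GRCm38), stood at a log2 fold change of 2.12 ± 0.25 (standard error, adjusted p = 5.38e-15). Sfxn1, a mitochondrial serine transporter, had 2.09 ± 0.19 (adjusted p = 5.57e-25) and Gldc, glycine decarboxylase, 2.08 ± 0.54 (adjusted p = 0.000831) in the authors' deposited table. Sox2, a transcription factor of pluripotent cells (chromosome 3, 34650405 to 34652461), had 2.08 ± 0.64 and an adjusted p of 0.005 in the authors' deposited table, where the chemokine gene Cxcl5 had 2.12 ± 0.64 and an adjusted p of 0.00419. The standard errors of these last genes were about the largest of any row, 0.640, and both calls were lost under the Benjamini-Yekutieli adjustment (0.0682 for Sox2 and 0.0573 for Cxcl5). The authors' deposited table gave log2 fold changes of 2.08 to 2.11 for Prkaa2 (a catalytic subunit of AMP-activated protein kinase), Plekha7 (a protein of adherens junctions), B4galt6 (a lactosylceramide synthase), Slc39a8 (a metal ion transporter) and Slc25a40 (a mitochondrial carrier), with standard errors of 0.25 to 0.33.

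With predicted genes left aside, the 10 lowest fold changes among called genes of that mean count lay between -2.94 and -2.28 in the authors' deposited table. Kcns1, a modifier subunit of voltage-gated potassium channels (chromosome 2, 164163619 to 164171113), had the lowest value of the authors' deposited table, -2.94 ± 0.29 (adjusted p = 5.93e-22). Adcy10, the soluble adenylyl cyclase of sperm, and Pde4c, a cyclic AMP phosphodiesterase, fell to -2.47 ± 0.36 and -2.34 ± 0.42 in the authors' deposited table. Mei1, needed for meiotic double-strand breaks, had -2.40 ± 0.31 (adjusted p = 1.02e-12), and Sox3, an X-linked transcription factor of undifferentiated spermatogonia (60891366 to 60893430), had -2.33 ± 0.29 (adjusted p = 1e-13) in the authors' deposited table. The matrix gene Emilin3 had -2.35 ± 0.19 (adjusted p = 4.88e-31), and Ighm, Tmc3 and Tbc1d30 had -2.48, -2.34 and -2.28 in the authors' deposited table.

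Thy1, the surface marker on which both populations had been selected, was higher in CDH1+/THY1+ cells by 1.40-fold in the authors' deposited table (log2 0.48 ± 0.18, adjusted p = 0.0292). That call was lost under the Benjamini-Yekutieli adjustment (adjusted p = 0.382). Cdh1 was not analysed here, so the direction of the table rests on its name. Hprt, a gene disrupted in DR4 feeder fibroblasts, was higher by 1.86-fold in the authors' deposited table (log2 0.90 ± 0.22, adjusted p = 0.000273). Xist, the RNA that silences an X chromosome in female cells, had a mean count of 102 and a log2 value of 0.82 ± 0.39 in the authors' deposited table and was not called (adjusted p = 0.0872). Members of the Y-linked list moved apart. Usp9y fell to -1.99 ± 0.21 (adjusted p = 1.86e-19) in the authors' deposited table and Zfy2 to -1.90 ± 0.32 (adjusted p = 9.13e-08). Ddx3y rose to 1.60 ± 0.31 (adjusted p = 2.22e-06) in the authors' deposited table, and Eif2s3y had 0.30 ± 0.14 without a call (adjusted p = 0.0824). The list as a whole, 7 genes with 1 higher and 2 lower, was not called by cameraPR (adjusted p = 0.258), with a median of 0.03 and a mean of -0.33.

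Germ cell genes were lower in CDH1+/THY1+ cells across 4 lists. Of 34 genes of germ cell identity and the piRNA pathway, which silences transposons in the germline, 31 were lower and 1 was higher, and the counts adjusted over the list alone were also 31 and 1. Their median log2 fold change was -1.65 (quartiles -1.80 and -1.23), below all 10000 random lists, and cameraPR gave an adjusted p of 1.01e-48. In the same comparison the fibroblast marker list was higher, with a median of 0.65. In the authors' deposited table Tdrd1, a Tudor protein of piRNA granules, fell to -2.22 ± 0.20 (adjusted p = 2.46e-27), the piRNA helicase gene Mov10l1 to -1.84 ± 0.16 (adjusted p = 1.16e-27), Tex15 to -1.76 ± 0.13 (adjusted p = 7.53e-39) and Rnf17 to -1.27 ± 0.12 (adjusted p = 1.03e-22).

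Of 36 genes of undifferentiated spermatogonia, 20 were lower and 1 was higher (22 and 1 adjusted over the list alone). The median was -0.87, with an adjusted p of 9.86e-09 by cameraPR. Zbtb16, a repressor that maintains spermatogonial stem cells, fell to -1.86 ± 0.18 (adjusted p = 7.29e-23), the adhesion gene Mcam to -1.10 ± 0.14 and the RNA-binding protein gene Dnd1 to -1.15 ± 0.16 in the authors' deposited table. Of 14 genes of differentiating spermatogonia, 8 were lower and 1 was higher (9 and 1 adjusted over the list alone). The median was -1.28, with an adjusted p of 2.2e-06 by cameraPR. The sex determination factor gene Dmrt1 fell to -1.75 ± 0.22, the transcription factor gene Sohlh2 to -1.38 ± 0.16, the X-linked Tex11 to -1.67 ± 0.20 and the Y-linked Uba1y to -1.75 ± 0.21 in the authors' deposited table, all with adjusted p-values of 1.3e-13 or less. Of 29 genes of meiotic chromosomes and recombination, 20 were lower and 0 higher (21 and 2 adjusted over the list alone). The median was -1.19, with an adjusted p of 6.84e-12 by cameraPR. Sycp3, a component of the synaptonemal complex, fell to -1.68 ± 0.19, Syce1 of the same complex to -1.34 ± 0.18, and M1ap to -1.36 ± 0.18 in the authors' deposited table. The spermatid list had 5 lower genes and 1 higher of 14, the same adjusted over the list alone, and a median of -0.95, below all 10000 random lists, but was not called by cameraPR (adjusted p = 0.132). It was called on the fold changes (adjusted p = 0.000518) and on ranks (adjusted p = 0.028), and the other 7 of its 21 listed symbols were not analysed here. Its lower members Ldhc, Hspa1l and Spaca1, at -1.23 ± 0.29, -1.78 ± 0.52 and -1.13 ± 0.35, had mean counts of 94.8, 14.1 and 36.4 in the authors' deposited table, against 2050 for Odf2, a centrosomal and sperm tail gene that rose to 1.23 ± 0.20.

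**Figure D2:**
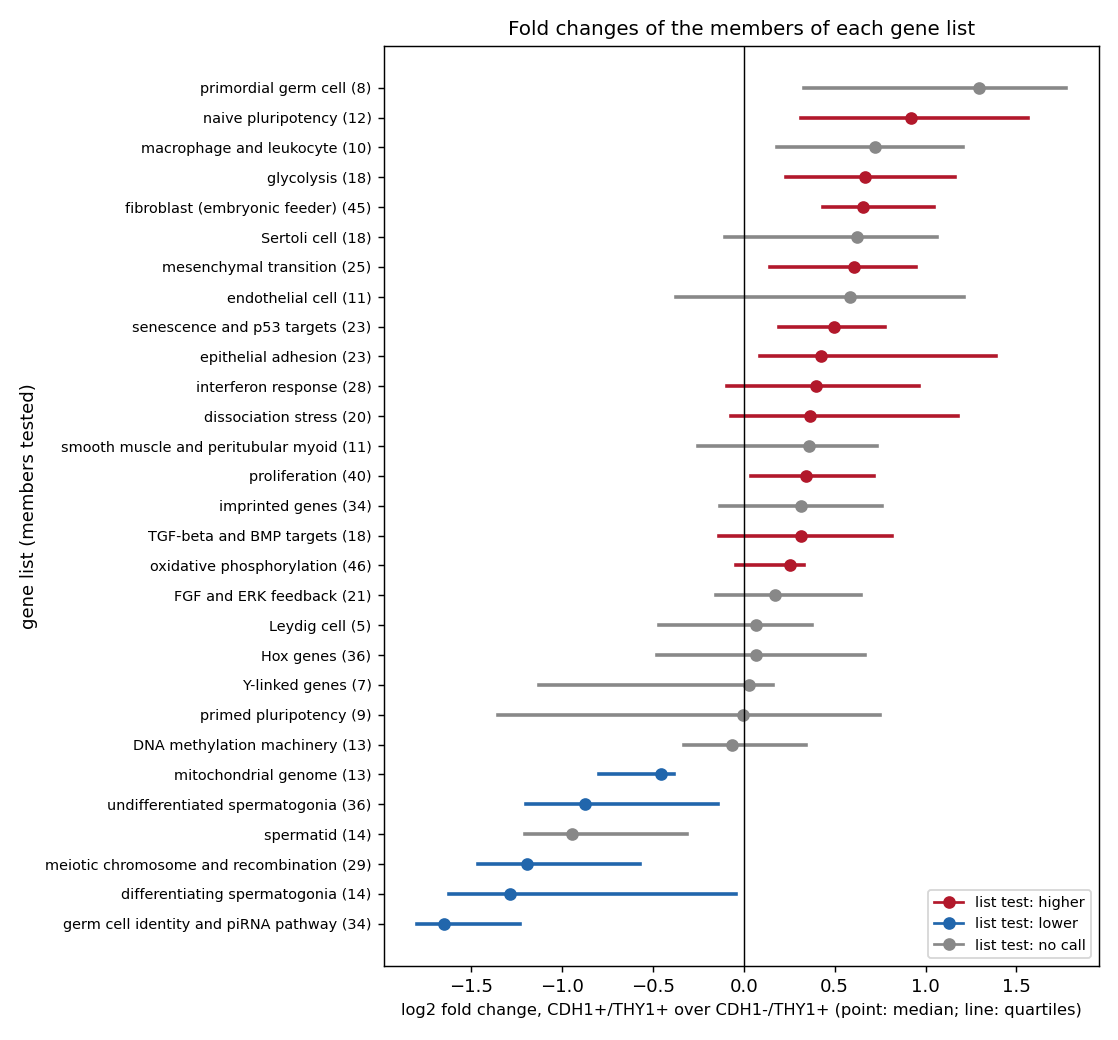
Median (point) and quartiles (line) of the log2 fold change, CDH1+/THY1+ over CDH1-/THY1+, of the members of 29 gene lists, computed from the authors' deposited table; colour shows the call of cameraPR at an adjusted p under 0.05 and brackets the number of members with a p-value. The 5 lists called lower are 4 germ cell lists and the mitochondrial genome, and 11 lists were called higher.

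Genes of naive pluripotency were higher in CDH1+/THY1+ cells. Of 12 members with a p-value, 7 were higher and 1 was lower (8 and 1 adjusted over the list alone). The median was 0.92, with an adjusted p of 0.00792 by cameraPR. The other 16 of the 28 listed symbols were not analysed here, so the median and the test do not cover them. Beside Sox2, Tbx3 had 1.96 ± 0.32 (adjusted p = 1.73e-08), Zfp42, known as Rex1, 1.93 ± 0.56 (adjusted p = 0.00263), Rex2 1.44 ± 0.35 (adjusted p = 0.000299) and Dppa4 1.27 ± 0.31 (adjusted p = 0.000253) in the authors' deposited table. Standard errors of the list's members were large for their mean counts, with a median percentile of 93.5 among genes of like mean count. The call ended when the tenth of genes with the largest such standard errors was left out, which left 4 members (adjusted p = 0.729), and when the members with the 2 largest statistics were left out (adjusted p = 0.0864). The fibroblast marker list was higher in the same comparison, and of 33 genes with few reads that had at least 75% of them in 1 library, 31 had them in the same unnamed library. These 31 include 11 genes without a p-value, which entered no list test. Of 8 primordial germ cell genes, 6 were higher and 2 lower, the same adjusted over the list alone, with a median of 1.29, above all 10000 random lists, and the other 6 of 14 listed symbols were not analysed here. The list was not called by cameraPR (adjusted p = 0.0816), but was called on the fold changes (0.00605), without members shared with other lists (0.00813) and without its 2 largest members (0.0312). The receptor gene Kit had 1.31 ± 0.24 (adjusted p = 7.33e-07), the transcriptional repressor gene Prdm1 1.73 ± 0.38 (adjusted p = 5.35e-05) and Ifitm3 0.82 ± 0.16 (adjusted p = 1.97e-06) in the authors' deposited table. Kit is also a marker of differentiating spermatogonia, the 1 gene of that list that was higher. The primed pluripotency list had 2 higher and 4 lower of 9 genes, the same adjusted over the list alone, a median of 0.00 and no call (adjusted p = 0.105, direction of the test lower), and the other 6 of 15 listed symbols were not analysed here. Pou3f1 fell to -1.47 ± 0.28, Foxa2 to -1.35 ± 0.35 and the DNA methyltransferase gene Dnmt3a to -0.65 ± 0.14 in the authors' deposited table.

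Genes of fibroblasts, the feeder cell type, were higher as a group. Of 45 members, 20 were higher and 0 lower (22 and 0 adjusted over the list alone). The median was 0.65, with an adjusted p of 3.93e-07 by cameraPR. The matricellular gene Ccn1 had 1.21 ± 0.16 (adjusted p = 6.7e-13), the actin-binding caldesmon gene Cald1 1.21 ± 0.17 (adjusted p = 1.6e-11), the hyaluronan receptor gene Cd44 1.14 ± 0.23 (adjusted p = 5.55e-06) and fibronectin, Fn1, 0.72 ± 0.14 (adjusted p = 6.13e-06) in the authors' deposited table. The list's median standard error percentile was 93. Without the tenth of genes with the largest standard errors for their mean, 18 members remained, with an adjusted p of 7.87e-05 by cameraPR. Of 102 genes without a p-value in the authors' deposited table, 98 had a fold change above 0, and the 11 whose reads per library were recovered had 80.4% to 100% of them in 1 unnamed library. Of 25 mesenchymal transition genes, 13 were higher and 1 was lower (14 and 1 adjusted over the list alone). The median was 0.61, with an adjusted p of 0.000528 by cameraPR. Its member Inhba, an activin subunit gene, had 1.26 ± 0.31 and the fibronectin receptor subunit gene Itga5 0.83 ± 0.16 in the authors' deposited table. Among TGF-beta and BMP targets, 5 of 18 were higher and 2 lower (8 and 2 adjusted over the list alone). The median was 0.31, with an adjusted p of 0.0392 by cameraPR, which became 0.134 with a preset correlation of 0.05. Id2 had 1.85 ± 0.35, Bmp4 1.13 ± 0.27 and Smad7 0.79 ± 0.19 in the authors' deposited table. The epithelial adhesion list, the programme to which CDH1 belongs, had 8 higher and 2 lower of 23 (9 and 2 adjusted over the list alone). The other 12 of its 35 listed symbols were not analysed here. The list's median was 0.42, with an adjusted p of 0.045 by cameraPR, which became 0.152 with a preset correlation of 0.05. The desmosomal gene Pkp2 rose to 1.36 ± 0.30 and Cd24a to 0.94 ± 0.21, but the tight junction genes Ocln and Marveld2 fell to -0.98 ± 0.21 and -1.11 ± 0.29 in the authors' deposited table.

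Marker lists of other cell types of the testis were not called as groups by cameraPR. Sertoli cell genes had 2 higher and 3 lower of 18 (adjusted p = 0.414, median 0.62). Kitl rose to 1.09 ± 0.39 in the authors' deposited table, while Trf, Sox8 and Defb36 fell to -1.10 ± 0.28, -1.12 ± 0.36 and -1.90 ± 0.58. Leydig cell genes had 0 higher and 1 lower of 5 (adjusted p = 0.756, median 0.07, direction of the test lower). The ferredoxin gene Fdx1 fell to -0.46 ± 0.18 in the authors' deposited table, a call over all genes but not adjusted over the list alone. Star and Cyp11a1, at -0.49 ± 0.43 and 0.52 ± 0.62, were not called in the authors' deposited table. Smooth muscle genes had 3 higher and 1 lower of 11 (adjusted p = 0.217). Cnn1 was at 1.60 ± 0.41 in the authors' deposited table, Myl9 at 0.78 ± 0.14, Smtn at 0.69 ± 0.21 and Mylk at -0.83 ± 0.22. Macrophage and leukocyte genes had 3 higher and 1 lower of 10 (adjusted p = 0.132, and 0.0276 on the fold changes). The lysosomal gene Cd68 was at 1.65 ± 0.33, Mrc1 at 1.21 ± 0.44, Ptprc at 1.52 ± 0.51 and H2-Aa at -1.58 ± 0.63 in the authors' deposited table. The mean counts of Ptprc and H2-Aa were 13.9 and 6.28. Endothelial genes had 2 higher and 1 lower of 11 (adjusted p = 0.756). In the authors' deposited table the transcription factor gene Erg fell to -2.14 ± 0.26, Eng rose to 1.18 ± 0.33 and Tie1, with a mean count of 4.58, to 1.58 ± 0.63. Cd34 had 0.95 ± 0.42 in the authors' deposited table and was not called. Among random lists matched on mean count the medians lay at percentiles of 99.9 for Sertoli, 98.7 for macrophage, 98.3 for endothelial, 90.6 for smooth muscle and 58.8 for Leydig cell genes. Of the listed Sertoli, Leydig and macrophage symbols, 4 of 22, 6 of 11 and 7 of 17 were not analysed here. In the Sertoli, smooth muscle, macrophage and endothelial lists the counts adjusted over the list alone were those over all genes.

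Proliferation and glycolysis genes were higher as groups in CDH1+/THY1+ cells, as were the fibroblast markers in the same comparison. Of 40 proliferation genes, 17 were higher and 1 was lower, the same adjusted over the list alone. Their median was 0.34, with an adjusted p of 7.99e-05 by cameraPR. The ribonucleotide reductase gene Rrm2 had 1.81 ± 0.24 (adjusted p = 1.03e-12), the mitotic kinase gene Cdk1 1.24 ± 0.18 (adjusted p = 2.1e-10), Ube2c 1.15 ± 0.17 and the survivin gene Birc5 1.34 ± 0.24 in the authors' deposited table. Of 23 senescence and p53 target genes, 9 were higher and 0 lower, the same adjusted over the list alone. Their median was 0.49, with an adjusted p of 0.00659 by cameraPR (0.0543 with a preset correlation of 0.05). The list's median standard error percentile was 92.5. Bbc3, the pro-apoptotic PUMA gene, had 1.49 ± 0.27, Gdf15 1.56 ± 0.43, Eda2r 0.84 ± 0.22 and Zmat3 0.84 ± 0.27 in the authors' deposited table. Glycolysis genes had 10 higher and 1 lower of 18 (11 and 1 adjusted over the list alone), with 4 of 22 listed symbols not analysed here. The list's median was 0.67, with an adjusted p of 0.000229 by cameraPR. Without the tenth of genes with the largest standard errors for their mean, 10 members remained and the adjusted p was 0.0773. Phosphofructokinase, Pfkl, had 1.76 ± 0.27, lactate dehydrogenase, Ldha, 1.51 ± 0.31, Tpi1 1.39 ± 0.26 and Gapdh 1.09 ± 0.20 in the authors' deposited table. Of 46 nuclear genes of oxidative phosphorylation, 12 were higher and 3 lower, the same adjusted over the list alone. Their median was 0.25, with an adjusted p of 0.0226 by cameraPR, which became 0.152 with a preset correlation of 0.05. That call was also lost on the fold changes (0.284), without the trend with exon length and GC content (0.127), without the 2 largest members (0.0864) and with a mean count of at least 10 (0.0538). Cox7b had 1.13 ± 0.15, Cox5a 0.73 ± 0.19, Uqcrc2 0.66 ± 0.15 and Ndufa6 0.59 ± 0.15 in the authors' deposited table. Transcripts of the mitochondrial genome moved the other way, with 8 lower and 1 higher of 13 (9 and 1 adjusted over the list alone). The list's median was -0.45, with an adjusted p of 0.0143 (0.0544 with a preset correlation of 0.05). The authors' deposited table gave a 2.01-fold lower level for mt-Nd3 (adjusted p = 0.000335) and log2 fold changes of -0.81 ± 0.19 for mt-Atp6, -0.79 ± 0.16 for mt-Atp8 and -0.69 ± 0.20 for mt-Nd1.

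Genes that respond to cell dissociation and to interferon were also higher as groups. The dissociation stress list had 9 higher and 2 lower of 20, the same adjusted over the list alone. The median fold change was 0.36 (log2), with an adjusted p of 0.0143 by cameraPR (0.0803 with a preset correlation of 0.05). That call was also lost without the 2 largest members (0.123) and without the tenth of genes with the largest standard errors (0.346). The small heat shock gene Hspb1 had 2.07 ± 0.30 (adjusted p = 1.99e-10), the immediate early gene Ier2 1.81 ± 0.40, Klf6 0.80 ± 0.14 and Dusp1 0.76 ± 0.19 in the authors' deposited table. The interferon response list had 10 higher and 2 lower of 28, the same adjusted over the list alone. The median fold change was 0.40 (log2), with an adjusted p of 0.0143 by cameraPR (0.0997 with a preset correlation of 0.05). Without its 2 largest members this list lost its call as well (0.123). In the authors' deposited table Bst2, the antiviral tetherin gene, had 1.58 ± 0.18 (adjusted p = 3.33e-16), the RNA sensor gene Ddx58 1.35 ± 0.20 and the immunoproteasome gene Psmb8 2.04 ± 0.41, while the transcription factor gene Irf1 fell to -1.07 ± 0.24 (adjusted p = 8.12e-05).

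The FGF and ERK, DNA methylation, imprinted and Hox lists held members that moved both ways and were not called as groups by cameraPR. FGF and ERK feedback genes had 6 higher and 3 lower of 21 (adjusted p = 0.414). In the authors' deposited table the FGF receptor gene Fgfr2 rose to 1.07 ± 0.18 and Spred3 to 1.43 ± 0.34, while Fgfr3 fell to -0.98 ± 0.24 and the ERK phosphatase gene Dusp5 to -0.87 ± 0.19. DNA methylation genes had 1 higher and 2 lower of 13 (adjusted p = 0.635). Tdg rose to 0.73 ± 0.21 and Tet3, an enzyme that oxidises methylcytosine, fell to -1.09 ± 0.23 in the authors' deposited table. Imprinted genes had 9 higher and 3 lower of 34 (adjusted p = 0.105, and 0.0467 on ranks). Sgce was at 1.45 ± 0.23, Impact at 0.87 ± 0.18, Inpp5f at -0.82 ± 0.17 and Dlk1 at -1.55 ± 0.26 in the authors' deposited table. Hox genes had 3 higher and 2 lower of 36 (2 and 2 adjusted over the list alone, adjusted p = 0.805 by cameraPR). Hoxd13 was at 1.74 ± 0.60, Hoxb7 at -1.35 ± 0.33 and Hoxb13 at -1.44 ± 0.46 in the authors' deposited table. The medians of the FGF, DNA methylation, imprinted, Hox, Y-linked and primed pluripotency lists lay at percentiles of 82.1, 34.1, 97.8, 65.9, 51.5 and 46.4 among random lists. Those of the 11 lists called higher lay at 93.2 to 100, and that of the mitochondrial genome at 1. Of the listed DNA methylation and imprinted symbols, 4 of 17 and 7 of 41 were not analysed here. For the Y-linked list and for the FGF, DNA methylation and imprinted lists the counts adjusted over the list alone were those over all genes.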

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

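Every test in this part was chosen after the values had been seen, except the check on Hprt, Xist and the Y-linked list.

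The authors' deposited table held 102 genes with a mean count, a fold change and a standard error but no p-value, which therefore enter no call and no list test. They stood out as a signal outside the comparison: 98 of them (96.1%) had a fold change above 0, and 40 had a mean count of at least 100. DESeq2 leaves the p-value of a gene empty when 1 library's count is extreme for it. With names chosen after the values were seen, and predicted genes left aside, the most abundant were C3, Rn7s1, Aldh1a1, Sned1, Serping1, Tgfbi and Col5a3. Their log2 fold changes ran from -0.74 for Rn7s1 to 1.62 for Tgfbi, with standard errors of 0.56 to 0.64.

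Counting noise of genes with few reads would not reach the 9 of these genes that had a mean count of at least 1000. A single library that stands apart from the others was the explanation whose prediction the recoverable values met. For 11 of the 102 genes the reads of each library could be worked out from the mean count, and in 11 of 11 the same unnamed library held most of the reads, 80.4% to 100%. The log2 fold changes of these 11 genes were all above 0. Ang5 had 37 of its 37 reads there and Pcdhgb8 17 of 18. An empty p-value by itself needs an extreme library, but not the same library for every gene. Whether that library differs by its culture, by the cells that passed the sort or by its preparation stays open, as the libraries carry no names and no test separated these. Whether the higher fibroblast list rests on that library was not tested, since reads per library were not recovered for abundant genes.

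The lower germ cell genes were weighed against the make-up of the samples. Hprt, Xist and the Y-linked list had been chosen beforehand as a check of feeder cells, and gave no single answer. Hprt, disrupted in the feeders, was higher in CDH1+/THY1+ cells (0.90 ± 0.22). Xist, at 0.82 ± 0.39, and the Y-linked list were not called. A larger share of feeder fibroblasts in CDH1+/THY1+ cells would raise the abundant fibroblast genes about alike only if other cells held little of their RNA. With a mean count of at least 1000, 6 of 39 (15.4%) had an upper 95% limit below their median of 0.65. Among them were Lox at -0.08, Postn at 0.04 and Mmp2 at 0.10. Rises can differ with a gene's level in the other cells, so this test cannot exclude a larger feeder share. Of the 45 list members, 20 were called higher and 0 lower. Fewer germ cells with no other change would lower all germ cell genes about equally only if other cells held little of their RNA. Undifferentiated spermatogonia genes with a mean count of at least 100 numbered 28. Of these, 20 (71.4%) had a lower 95% limit above the germ cell identity median of -1.65. Among them were Gfra1 at -0.99, Etv5 at 0.20 and Cd9 at 0.51. Genes also expressed in other cells would fall less, so this test cannot exclude fewer germ cells. In the germ cell identity list 31 of 34 genes were lower, with quartiles of -1.80 and -1.23. Removing a trend with exon length and GC content left the germ cell identity median at -1.75. A shift in make-up, a difference in state between the sorted populations, or both may account for the pattern as hypotheses. No test separated them.

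The 532 called genes not analysed here were weighed as well. If they had been missing without regard to the test, 418.4 of them were expected to have a p-value above 0.00082, the p-value of a gene at the highest fold change with the largest standard error, and 0 had one. An upper limit of 2.14 on the log2 fold change of the rows, which predicts 0 such genes, may account for them. Under it the strongest increases in CDH1+/THY1+ cells lie outside the account given here. List medians and list tests would then lack any members above that limit, while 69 rows as far below 0 were kept. No biological explanation was tested for this pattern.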

How the results depend on the processing

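The alternatives that left out rows as far below 0 as the table ends above it, genes in the top 10% of standard errors for their mean, or a trend with exon length and GC content were chosen after the data were seen; the others were fixed before. The table holds no values per library, so fits with other size factors, without a low-count filter, with a culture left out, and other splits of the 6 samples were not run. No paired analysis was possible because the columns carry no culture names, although both populations share RP7, RP5 and WT1. In simulated data with the real standard errors 46.3% of 2-fold changes were called over genes of all mean counts. Only 200 of 22330 simulated genes were changed, whereas 33.5% of the real genes were called. The adjustment was therefore stricter in the simulation, and 46.3% is not the sensitivity of the real comparison. Depth was not separated from the spread between samples.

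The counts of higher and lower genes stayed within 1.5 times of 3292 and 3146 in 13 of 20 values. The others moved under stricter thresholds, which fewer genes can pass: an adjusted p under 0.01 left 2107 higher genes, Benjamini-Yekutieli 1666 higher and 1967 lower, at least 2-fold 1435 and 1256, and at least 4-fold 91 and 114. As the rows end at a log2 fold change of 2.14 on the higher side, the 91 cover only values from 2 to 2.14. Of the genes changed at least 2-fold, 740 higher and 614 lower had a mean count of at least 100. Thy1 lost its call under Benjamini-Yekutieli (0.382), while Hprt kept its call and Xist had none under any of the 3 adjustments tried. For the genes chosen by the naming rule, 374 of 390 values kept their side of the threshold and 16, all under Benjamini-Yekutieli, lost the call: Thy1, Sox2, Cxcl5, Spaca1, Defb36, Sox8, Kitl, Fdx1, Smtn, Ptprc, Mrc1, H2-Aa, Tie1, Hoxb13, Hoxd13 and Zmat3.

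Of 16 gene lists called, 7 were called under all 9 alternatives: germ cell identity, undifferentiated and differentiating spermatogonia, meiotic chromosomes, fibroblast, mesenchymal transition and proliferation. The meiotic and proliferation lists had no shared members to leave out. Of 260 values, 226 kept their side, 26 lost the call, 8 gained it, and no call changed direction. The Leydig list had too few members for the alternative with a mean count of at least 10. Adjusted p-values that lost the call were as follows. With a preset correlation of 0.05: epithelial adhesion and oxidative phosphorylation 0.152, TGF-beta and BMP targets 0.134, interferon 0.0997, dissociation stress 0.0803, mitochondrial genome 0.0544, p53 targets 0.0543. Without the 2 largest members: naive pluripotency, oxidative phosphorylation and mitochondrial genome 0.0864, TGF-beta 0.219, dissociation stress and interferon 0.123. With a mean count of at least 10: epithelial adhesion 0.0848, TGF-beta 0.0829, oxidative phosphorylation 0.0538. Without shared members: epithelial adhesion 0.0505, TGF-beta 0.139. On fold changes: oxidative phosphorylation 0.284, mitochondrial genome 0.0537. Without the trend: oxidative phosphorylation 0.127. Without large standard errors: naive pluripotency 0.729, epithelial adhesion 0.442, dissociation stress 0.346, glycolysis 0.0773, TGF-beta 0.0565. Values that gained a call were, on fold changes, spermatid 0.000518, primordial germ cell 0.00605 and macrophage 0.0276, on ranks, spermatid 0.028 and imprinted genes 0.0467, for primordial germ cell 0.00813 without shared members and 0.0312 without the 2 largest, and for primed pluripotency 0.0465 without large standard errors. The cause of the lost and gained calls was not tested.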

Other observations

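Gene families grouped by symbol, chosen after the values were seen and each limited to genes with a mean count of at least 10, were tested as the lists were, with adjustment over 8 families. The Mage family had 9 lower and 0 higher of 15, with a median log2 fold change of -1.21 (adjusted p = 0.000192 by cameraPR). The X-linked Rhox homeobox family had 5 lower and 0 higher of 9, with a median of -0.98 (adjusted p = 0.000707). Potassium channel genes of the Kcn family had 15 lower and 4 higher of 44 (median -0.41, adjusted p = 0.00886), and Usp deubiquitinase genes 19 lower and 6 higher of 49 (median -0.19, adjusted p = 0.0029). The Kcn call was lost with a preset correlation of 0.05 (0.0812) and without the 2 largest members (0.0596), and the Usp call with that correlation (0.0687) and on the fold changes (0.0995).

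Ribosomal protein genes had 30 higher and 4 lower of 84 (median 0.25, adjusted p = 0.000113 by cameraPR) and replication-type histone genes 23 higher and 7 lower of 63 (median 0.44, adjusted p = 0.00257). Protocadherin genes had 9 higher and 1 lower of 38 (median 0.52, adjusted p = 0.0106), with a median standard error percentile of 88.75. With a preset correlation of 0.05 the histone (0.0687) and protocadherin (0.0812) calls were lost, as they were without the tenth of genes with the largest standard errors for their mean (0.0575 and 0.0513). The ribosomal call was lost on the fold changes (0.0547). Adjusted over the family alone, 2 Mage genes were higher and 9 lower, 6 Rhox genes lower, 6 Usp genes higher and 20 lower, 31 ribosomal genes higher and 4 lower, and 6 protocadherin genes higher and 1 lower, while the Kcn and histone counts were those over all genes. The zinc finger Zfp family, 346 genes with 66 higher and 77 lower (68 and 80 over the family alone), was not called (adjusted p = 0.628). Members of these families share sequence, so reads could be split between them, and the families were picked because of their values.

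Large standard errors were unevenly spread over the lists. Among genes of like mean count the median percentile was 94 for epithelial adhesion, 93.5 for naive pluripotency and 93 for fibroblast genes, and 26.25 for oxidative phosphorylation. Germ cell lists called lower also had large ones: 88 for undifferentiated and 87 for differentiating spermatogonia, 78.5 for germ cell identity and 65.5 for meiotic chromosomes. Among 2779 rows with a mean count under 8 and at least 18 reads, 33 had at least 75% of their reads in 1 library, 31 of them in the same unnamed library that held the reads of the genes without a p-value, and 2 in 1 other. The 31 include the 11 genes without a p-value whose reads were recovered, so these counts overlap.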
